A study of Homo sapiens with 30 samples.

How the data were processed

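HEK 293T cells were transfected with deaminase constructs, guides or GFP, and poly(A) RNA was taken after 60 h; libraries were made from 300 ng of RNA and sequenced as paired 100 bp reads, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.6.0c, SAMtools and the genome build GRCh38.p12, without their settings. The labels say that the 4 untransfected samples are separate lanes or runs of 1 library, so they are technical repeats, and the 26 other samples are 1 library for each condition.

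The authors deposited 2 tables with 1 line per site. The first gives, per the file headers and the range of its values, the fraction (share, 0 to 1) of reads with the edited base at each site and sample, with no read counts. The second gives, for the same sites, the authors' deposited adjusted p-values. The header names neither the test nor its reference sample, and both are not given in the sources used here. How the sites were selected is not stated either. A check of the p-value table found an adjusted p under 0.01 in at least 1 column at 382976 of 382978 sites, with a highest minimum of 0.0505, so the list holds sites that had passed in some library. In the table of shares 1 column carried no sample name and was not used. It was left unmapped, so the first untransfected run was not analysed here, and the control was the mean of runs 2, 3 and 4. Depth per sample is unknown. Shares have no counting interval for that reason, and PCR reads without molecular identifiers would in any case not be independent molecules.

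The plan fixed before the data were examined was an exact test of read counts per site. Because the tables give shares and p-values alone, its stated fallback was used. A site counted as called in a library when the authors' adjusted p was under 0.01 and its share was higher than the untransfected mean. Samples were grouped by the construct, localisation signal and guide in their labels. Comparisons of constructs by 4 factors followed (E-to-Q against wild type in 10 matched pairs, NLS against NES in 8, with against without guide in 11, ADAR2 against ADAR1 in 8), each as an exact two-sided sign-flip permutation test of the log2 ratios of called sites, with Benjamini-Hochberg adjustment over 4. The same test was run on the mean share over the 382863 sites called in any deaminase library. Constructs are the units of these tests, and pairs that share a construct are not independent of each other, so a p-value describes this set of constructs. Differences between effects were tested by exact permutation of pairs, 13 tests in all. This took no account of how the pairs are matched on other factors. Each difference within MCP fusions enters under both of its factors.

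Single sites were compared in the 16 MCP libraries with limma 3.58.1 (R 4.3.3) on arcsine square roots of the shares, with enzyme, variant, localisation and guide as main effects, an intensity trend, Benjamini-Hochberg adjustment per factor over 382978 sites and a threshold of 0.05. With 1 library per cell of this design, the spread comes from 11 residual degrees of freedom, which hold interactions and noise between libraries. The adjustment covers both directions of a factor together, so it does not bound false calls within the rarer direction. On simulated data 50 sites were changed by guide at each size. The fit recovered 6% of sites changed by 0.1 on the arcsine scale, 50% at 0.2, 96% at 0.3 and 96% at 0.4, with 8 false calls. These data held independent normal noise of the fitted spread, with no effect of the other factors and no interactions. The rates therefore do not show power or false calls in the real libraries. Planted gene lists with calls 1.3 times as frequent were all recovered. All other simulated genes shared 1 call rate per library, without the spread between real genes, so this does not show power or false calls in these data. Of the 100 random splits planned, 50 were run, the real one included, because of computing time.

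Sites were annotated with GENCODE release 29 on GRCh38 using bedtools 2.31.1 and Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and plots were drawn with matplotlib 3.10.9. At the positions as given, 99.86% of 352930 sites in exons of 1 gene were adenosine on the transcript strand, against 23.6% and 23.7% one base to either side, so positions are 1-based. Coding sequence held 245836 sites, 3′ UTRs 111883, 5′ UTRs 16228, noncoding exons 6224 and introns 1454. For 27746 sites exons of more than 1 gene or of both strands overlap, and the library kit is not stated to keep strand. Neighbouring bases come from the transcript sequences. The background was all adenosines of 1 annotated transcript for each of the 9041 genes with a listed exonic site. These genes are themselves selected, since sites were listed because some library called them. The plan named covered sites not called as the background. In this selected list those are nearly all called in other libraries, and they are given beside it. Exact Clopper-Pearson intervals at 95% on shares of called sites were computed for single libraries and cover counting error of sites only. Gene lists were compared with 10000 random gene lists of the same size matched on the number of listed sites.

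Sites named in the text follow a rule fixed beforehand, with at most 1 site per gene in each part. They are the 20 sites with the largest mean increase among those called in at least 11 deaminase libraries, and for each factor the 10 sites in each direction with the largest mean difference over 8 pairs, past the limma threshold and of the same sign in all 8. For guides outside MCP they are the 5 sites with the largest gain in full-length ADAR2 and in the Cas13b fusion, and in lists of known substrates and of the ADAR family at most 3 sites per gene called in at least 4 libraries. The report prints part of them, and some items are withheld for evaluation and not reported here.

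Alternatives tried were other thresholds on the adjusted p (0.05, and 0.001 added later), a minimum increase of 5 points, an increase of 10 points without a p-value (added later), GFP as the reference for a higher share, each untransfected run or matched pair left out, mean levels in place of counts, and in limma no trend, an interaction term, logits with a pseudocount of 0.01 or 0.05, and sites with a mean share of at least 2%. Those that need read counts were not run.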

Results

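The study measured A-to-G changes across the transcriptome of HEK 293T cells, a human embryonic kidney line, after transfection with RNA-guided adenosine deaminases. These enzymes convert adenosine to inosine, which is read as G in cDNA. The labels describe 30 samples of poly(A) RNA collected 60 h after transfection. In 16 of them the deaminase domain (DD) of ADAR1 or ADAR2 was fused to MCP, the coat protein that binds MS2 hairpins, and each fusion carried a nuclear localisation signal (NLS) or a nuclear export signal (NES). Each was tested as wild type or with a glutamate-to-glutamine substitution, E1008Q in ADAR1 or E488Q in ADAR2 (called E-to-Q here), known as more active forms, and each with and without an MS2 adRNA guide. Another 4 libraries expressed full-length ADAR2, wild type or E488Q, with and without a GluR2 adRNA, and 2 expressed Cas13b fused to ADAR2 DD (E488Q) with and without a Cas13b gRNA. Controls were 4 sequencing runs of 1 untransfected library, a GFP transfection and 3 transfections of a guide alone. Each other condition had 1 library, so no value of a single condition has a replicate error, and SDs are over constructs or over matched pairs of constructs. The values were the share of reads with G at 382978 sites, given without read counts, so the depth behind each share is unknown and no interval is given for it.

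Every library with a deaminase carried at least 3759 called sites, and no control more than 23. With a site called where the adjusted p in the authors' deposited table was under 0.01 and the share was above the untransfected mean, the 22 deaminase libraries had between 3759 and 226614 called sites in 1437 to 8576 genes. The fewest were in MCP-ADAR2 DD-NLS without guide and the most in MCP-ADAR1 DD (E1008Q)-NES without guide. From the same calls in the authors' deposited table, GFP had 6 sites, the MS2 adRNA alone 14, the GluR2 adRNA alone 18 and the Cas13b gRNA alone 23, and untransfected runs 2, 3 and 4 had 0, 1 and 4. The mean share over all sites was 0.153% in the untransfected runs, with an SD between the 3 runs of 0.162 percentage points at a site on average, and 0.938% to 11.4% in the deaminase libraries. The median level of called sites lay between 5.62% and 15.8%. Of all sites, 139818 were called in exactly 1 deaminase library, 25387 in at least 11, and 498 in all 22. Nearly every site listed had passed the threshold in some library (382976 of 382978), so shares of this table describe a selected set.

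**Figure D1:**
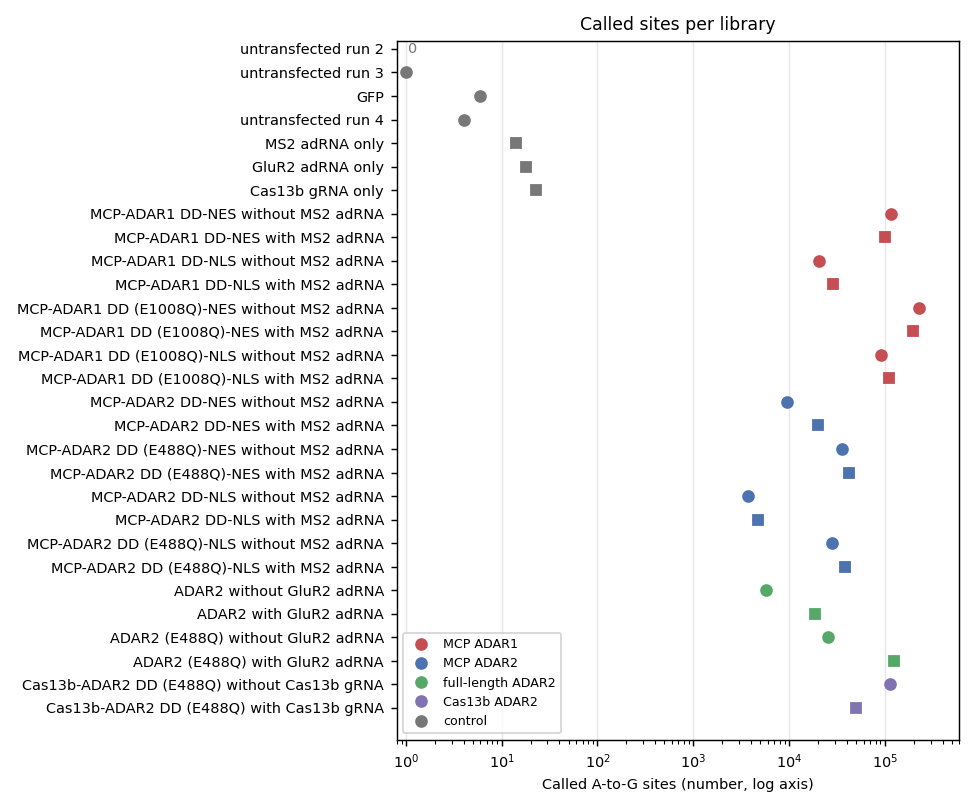
Number of called A-to-G sites per library on a log axis, 1 point per library, circles without guide and squares with guide, coloured by enzyme system. The 22 deaminase libraries lie between 3759 and 226614 sites, and the controls between 0, written at the left edge, and 23.

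The sites with the highest editing across constructs lay in protein-coding messages and in processed pseudogenes. At chr 19, position 48875699, the Q584R codon of PPP1R15A (ENSG00000087074.7), a regulatory subunit of the phosphatase that acts on eIF2 alpha, the share rose above the untransfected level by 60.5 ± 12.9 points (SD over 22 libraries) and the site was called in all 22. In SPNS1, which codes for a lysosomal transporter, the Y67C site at chr 16, position 28975351, gained 59.0 ± 15.8 points, and the S2267G site of FLNC, a filamin of muscle, at chr 7, position 128854583, gained 56.3 ± 20.0 points in the same mean. The S45G site of ATG4D, an autophagy protease, at chr 19, position 10544223, gained 54.5 ± 15.6 points and was called in all 22. In 3′ UTRs, TXNL4B (chr 16, position 72085322) gained 57.4 ± 10.5 points, SELENOT (chr 3, position 150627664) 56.1 ± 15.4 and COMMD9 (chr 11, position 36274513) 55.9 ± 13.4, each called in all 22 libraries. The largest mean increase, 76.8 ± 16.9 points, was at chr 19, position 23827412, in RPSAP58. Sites in the processed pseudogenes RPS2P5 (63.6 ± 25.2), HNRNPA1P7 (56.8 ± 26.1) and EEF1A1P5 (56.3 ± 26.6) were also among the 20 highest, and reads there can belong to the near-identical parent genes, so these positions are uncertain. The SPNS1 site overlaps another annotated gene.

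The E-to-Q substitutions went with more called sites in every matched pair, the question being how far the more active deaminase widens off-target editing. Protein amounts were not measured here, so the substitution cannot be told apart from different amounts of the constructs. Called sites from the authors' deposited table were 3.95-fold more numerous with the substitution, from 1.93-fold to 8.04-fold over 10 matched pairs. Among named sites, the Y122C site of WBP1L (chr 10, position 102812667) stood at 56.0% in E-to-Q and 6.65% in wild-type MCP libraries, a difference of 49.4 ± 10.4 points (SD, 8 pairs; limma adjusted p = 1.15e-05), and a 3′ UTR site of TUFT1 (chr 1, position 151582434) at 65.0% and 18.4% (46.6 ± 14.7 points; limma adjusted p = 2.25e-05). The other 8 of the 10 sites with the largest rise lay in pseudogenes, 6 of them relatives of ribosomal protein genes such as RPS27AP16 (52.9 ± 9.69 points). A small set went the other way. Shares fell with the substitution by 18.2 ± 4.28 points in the CMTM3 3′ UTR (chr 16, position 66613295), to 1.34% from 19.5% at BCAR1 G567G (chr 16, position 75235198), to 10.8% from 27.9% at ACIN1 E734G (chr 14, position 23078247), and to 6.48% from 20.9% at MOV10 K318R (chr 1, position 112691781), an RNA helicase. Over all sites, limma called 154870 as different between E-to-Q and wild type, 152112 higher and 2758 lower. The adjustment does not bound false calls among the lower ones taken alone.

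The mean log2 ratio of called sites was 1.98 ± 0.78 (SD, 10 pairs), higher in 10 of 10 (exact two-sided sign-flip p = 0.00195, the smallest possible; 0.00781 after Benjamini-Hochberg adjustment over 4 factors). The mean level over sites called in any deaminase library was 3.18 ± 1.70 points higher (exact p = 0.00195). The gain was 5.65-fold in NLS and 2.33-fold in NES fusions (difference of log2 ratios 1.28, exact p = 0.0286, the smallest possible, 0.124 after adjustment over 13 such tests). It was 4.66-fold in ADAR2 and 2.83-fold in ADAR1 (difference 0.72, exact p = 0.286). Neither difference passed adjustment, which the first could hardly have done with so few pairs. Fitted within NES or NLS libraries alone, limma called 44656 and 55787 sites.

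Fusions with the NLS edited fewer sites than those with the NES, and 3′ UTR sites were a smaller part of them. In the authors' deposited table called sites were 2.46-fold fewer with the NLS, from 1.12-fold to 5.67-fold over 8 pairs. A site in P4HA2 (L387L, chr 5, position 132203838), a collagen prolyl hydroxylase subunit, stood at 24.5% with NLS and 57.8% with NES, a fall by 33.4 ± 11.9 points. Also lower were 3′ UTR sites of ZC3HAV1, an antiviral zinc-finger protein (chr 7, position 139044104, 25.5% against 53.9%), VASP, an actin regulator (chr 19, position 45526737, 6.74% against 33.2%) and TMEM106B (chr 7, position 12234607, 4.05% against 30.0%). NFKB2 Y464C (chr 10, position 102399640) stood at 19.9% against 46.4%, and HIST1H4C H76R, in a histone H4 message (chr 6, position 26104174), at 11.1% against 37.3%. Higher with NLS were CLCN7 Y746C (chr 16, position 1447405), in a lysosomal chloride transporter, at 42.0% against 2.20% (39.8 ± 11.9 points), and DDX23 K245R, in a spliceosomal helicase (chr 12, position 48837543), at 19.8% against 0.889%. RAVER1 R565G (chr 19, position 10317602) stood at 53.8% against 33.9%. All these sites passed limma's adjusted threshold with the same sign in 8 of 8 pairs.

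Limma called 14555 sites by localisation, 152 higher and 14403 lower with the NLS. The adjustment does not bound false calls among the few higher ones taken alone. Of the 13348 lower sites with an annotated transcript context 41.6% lay in 3′ UTRs, against 4.03% of the 124 higher ones. Of the 338935 sites not past the threshold 28.95% did. The mean log2 ratio of called sites was -1.30 ± 0.83 (SD, 8 pairs; exact p = 0.00781, the smallest possible; 0.0104 adjusted), lower in 8 of 8, and the mean level fell by 2.2 ± 2.0 points (exact p = 0.00781). The reduction was 3.84-fold in wild-type and 1.58-fold in E-to-Q fusions (exact p = 0.0286, the smallest possible, 0.124 adjusted). The limma count moved from 6894 to 24355 with the transformation and model used.

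Fusions of the ADAR1 deaminase domain edited more sites than those of ADAR2, and a smaller set of sites went the other way. From the authors' deposited table, called sites were 5.22-fold fewer with ADAR2, from 2.90-fold to 12.3-fold over 8 pairs. A GATAD1 3′ UTR site (chr 7, position 92456822) stood at 1.84% with ADAR2 and 72.9% with ADAR1, FNDC3A T229A (chr 13, position 49145811) at 3.15% and 64.8%, and SNRPB T143A, in a core spliceosomal protein (chr 20, position 2463221), at 1.04% and 58.1%. 3′ UTR sites of KLHL15 (chr X, position 23985791, 0.694% and 58.4%), KAT6A, a histone acetyltransferase (chr 8, position 41930574, 1.34% and 57.1%), and DCK, deoxycytidine kinase (chr 4, position 71029868, 1.57% and 57.3%), were lower too. In the opposite direction, MICALL1 S337G (chr 22, position 37922411) stood at 47.8% with ADAR2 and 9.20% with ADAR1, APBA2 E200G (chr 15, position 29054483) at 43.9% and 8.62%, and a CNN2 3′ UTR site (chr 19, position 1038198) at 39.4% and 4.44%. Each of these differences passed limma's adjusted threshold with the same sign in 8 of 8 pairs, with an SD over pairs of 7.82 points at FNDC3A and 18.1 points at APBA2, the lowest and highest among them.

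Limma called 262829 sites by enzyme, 9949 higher and 252880 lower with ADAR2. The adjustment does not bound false calls among the higher ones taken alone. Sites entered the table by passing in some library, and how far the directions by enzyme and by variant depend on this was not tested. Amounts of the ADAR1 and ADAR2 fusions were not measured here, so the domain cannot be told apart from its amount. The mean log2 ratio of called sites was -2.38 ± 0.64 (SD, 8 pairs; exact p = 0.00781; 0.0104 adjusted), lower in 8 of 8, and the mean level fell by 4.39 ± 2.42 points. Limma called 14127 sites for the interaction of enzyme and variant. By enzyme it called 244090 sites with NES libraries alone and 69156 with NLS libraries alone.

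**Figure D2:**
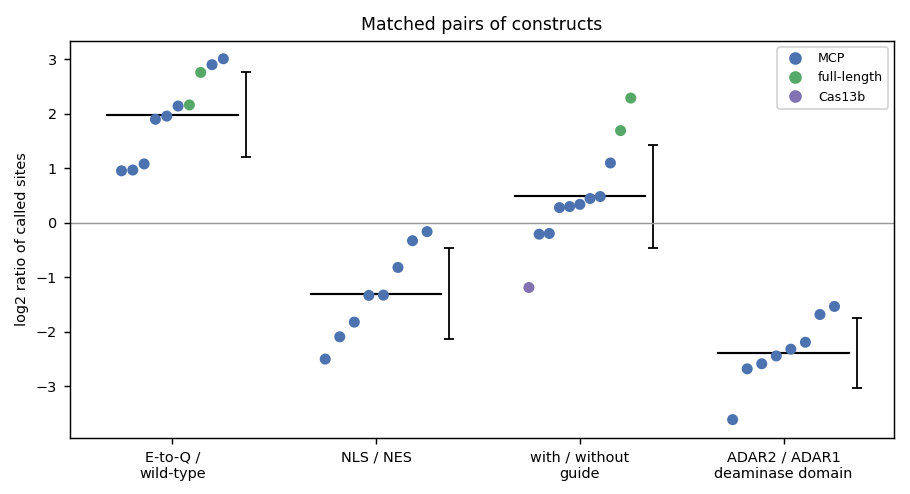
Log2 ratio of called sites in matched pairs of constructs, 1 point per pair, with the mean as a horizontal line and 1 SD as the error bar. All 10 E-to-Q pairs lie above 0, all 8 NLS pairs and all 8 ADAR2 pairs lie below 0, and 8 of 11 guide pairs lie above 0.

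The 2 enzymes' E-to-Q fusions shared most of the ADAR2 sites. By the calls of the authors' deposited table, 268249 sites were called in at least 1 E-to-Q MCP-ADAR1 library and 56531 in at least 1 E-to-Q MCP-ADAR2 library. Both held 49011 sites, 86.7% of the ADAR2 set and 18.3% of the ADAR1 set, where independent lists of these sizes would share 39596. That number counts only listed sites, which are listed because some library called them. The ADAR1 set alone held 70.0% of the listed sites, so this selection shapes the expected number. The excess over it cannot be read as a measure of sharing. The same untransfected mean set the direction of both sets, the reference behind the p-values is not named, and no control could be split or simulated without read counts, so part of the excess may come from a shared control.

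The guides' effect on the number of called sites did not pass its test, but a site called with every guide and never without lay in RAB7A, a late endosomal GTPase. That the RAB7A message is the guides' target comes from general knowledge of the study, not from the sources used here. The site at chr 3, position 128814202, in the 3′ UTR of RAB7A (ENSG00000075785.12, plus strand), has U before and G after the edited adenosine. In the authors' deposited table it passed in all 11 deaminase libraries with a guide and in 0 of 11 without. Its share was 25.0% ± 12.2 with guide (SD, 11 libraries, 7.00% to 41.9%) and 0.975% ± 0.886 without (at most 2.53%), a difference of 24.0 ± 12.2 points in 11 of 11 pairs (exact p = 0.000977, the smallest possible). The highest shares were 41.9% in MCP-ADAR1 DD (E1008Q)-NES, 41.6% in MCP-ADAR2 DD-NES and 36.7% in MCP-ADAR1 DD-NES. Full-length ADAR2 gave 27.6% and its E488Q form 26.8%, from 0% in both without guide, and the Cas13b fusion 11.6% against 2.53%. With guide, the 4 NES fusions averaged 37.0% ± 6.56 and the 4 NLS fusions 15.1% ± 8.23, lower in 4 of 4 pairs (exact p = 0.125, the smallest that 4 pairs allow). The labels do not name the target. The position is the one the rule for named sites put first, so its exact p belongs to a site chosen by its values; among all sites, limma gave it an adjusted p of 0.0480, a call lost without an intensity trend and with the interaction of enzyme and variant, where limma called 0 sites by guide (12126 and 14302 at an unadjusted p under 0.05).

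Within 50 nt of the target the table listed 6 other sites. At offset -8 (position 128814194) the share was 6.98% ± 8.34 with guide and 0.208% without, and at offset -9 (position 128814193) 6.05% ± 6.03 and 0.515%, each higher in 10 of 11 pairs (exact p adjusted over 7 sites 0.00684 in both). The highest value was 27.8% at offset -8 in MCP-ADAR1 DD (E1008Q)-NES. The other 4 sites did not pass. The gain at the target ranked 9th among all sites in MCP-ADAR2 DD-NES, 34th in MCP-ADAR1 DD (E1008Q)-NES, 37th in MCP-ADAR1 DD-NES and 13633rd in full-length ADAR2 (E488Q).

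**Figure D3:**
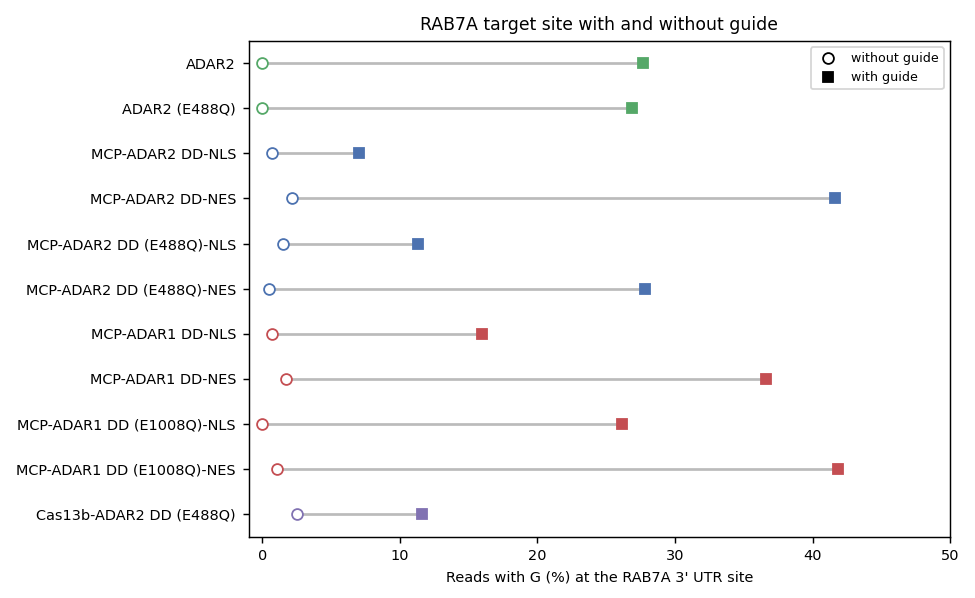
Reads with G (%) at the RAB7A 3′ UTR site for the 11 deaminase constructs, open circles without guide and filled squares with guide, joined by a line. With guide the shares run from 7.00% to 41.9%, and without guide none exceeds 2.53%.

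Across the whole set, called sites from the authors' deposited table were 1.40-fold more numerous with guide, with a range from 2.28-fold fewer in the Cas13b fusion to 4.87-fold more in full-length ADAR2 (E488Q). The mean log2 ratio was 0.48 ± 0.94 (SD, 11 pairs), higher in 8 of 11, and did not pass (exact p = 0.127). Without the Cas13b pair it was 0.65 (exact p = 0.0137). Limma called 3 sites by guide in the MCP libraries and 11666 at an unadjusted p under 0.05. Beside RAB7A these were SLC25A20 S183G (chr 3, position 48859616), in the mitochondrial carnitine carrier, with 13.5 ± 9.97 points, and XRCC1 K438R (chr 19, position 43546708), in a DNA repair scaffold, with 1.73 ± 1.06 points, both at 0% in the 8 libraries without guide. Their calls in the authors' deposited table numbered 1 and 2. In full-length ADAR2 the largest gains with guide were at 3′ UTR sites of RAB2B (68.3% against 4.17% on average over 2 pairs), GCC2 (61.1% against 10.4%) and TAF8 (56.5% against 6.17%), and in the Cas13b pair at REST (58.3% against 12.5%), a neuronal gene repressor, and HEXA (43.8% against 6.67%), a lysosomal hexosaminidase. These values have no replicate.

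Edited adenosines were mostly followed by G and rarely preceded by G. Over the 22 deaminase libraries, 65.3% ± 5.54 of called sites had G at the 3′ side, against 28.6% of the background adenosines. G at the 5′ side made up 7.82% ± 2.99, against 25.6%. UAG made up 11.7% ± 2.33, against 3.43%. Against the listed sites not called in the same library, nearly all called in others, the contrast was smaller. Those had a 3′ G in 57.95% ± 1.12 (lower than called sites in 22 of 22 libraries), a 5′ G in 12.9% ± 1.03 and UAG in 8.15% ± 0.610. Full-length ADAR2 (E488Q), without and with guide, went the other way for 5′ G and UAG. Its called sites had 5′ G in 14.1% and 14.2%, against 12.0% and 11.1% of those not called. UAG made up 8.18% and 7.59%, against 8.69% and 9.16%. E-to-Q libraries had a broader spread. Their share of sites with a 3′ G fell by 10.5 ± 2.04 points, that with a 3′ C rose by 7.17 ± 1.38 points and that with a 5′ G rose by 4.68 ± 1.02 points, each in 10 of 10 pairs (exact p = 0.00195; 0.0169 adjusted over 52 tests). Sites of MCP-ADAR2 fusions had 5′ A less often than those of MCP-ADAR1 fusions, 33.7% against 40.1%. They had 5′ C more often, 32.7% against 26.4%, both in 8 of 8 pairs (exact p = 0.00781, 0.0169 adjusted). No neighbouring base differed by guide after adjustment. The background counts equally each adenosine of 1 transcript per gene with a listed exonic site, and takes no account of expression.

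**Figure D4:**
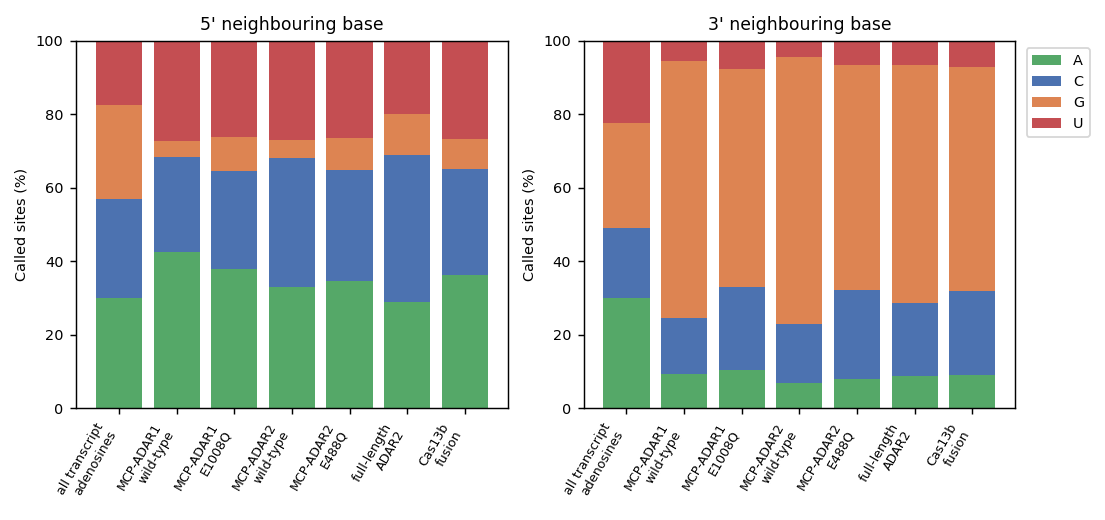
Share of called sites (%) by the base 5′ and 3′ of the edited adenosine, as stacked bars of the mean over the libraries of each group, with all adenosines of annotated transcripts at the left. A 3′ G follows 70.1% of sites in wild-type and 59.3% in E1008Q MCP-ADAR1 libraries, against 28.6% of all transcript adenosines.

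Coding sequence held 66.7% ± 9.86 of called sites and 3′ UTRs 27.3% ± 6.98. The background adenosines divide as 45.5% and 47.7% and listed sites not called as 64.4% and 29.9%. Of coding sites, 73.4% ± 1.53 changed the amino acid, against 74.98% of the coding background adenosines. NLS fusions had 4.07 ± 1.61 points fewer sites in 3′ UTRs (22.3% against 26.4%) and 3.29 ± 1.35 points more in coding sequence, in 8 of 8 pairs (exact p = 0.00781; 0.0169 adjusted). MCP-ADAR2 fusions had 22.2% of their sites in 3′ UTRs and MCP-ADAR1 fusions 26.5%, with the same p-values. Full-length ADAR2, outside these pairs, had 39.6%. Sites in 5′ UTRs were 4.10% with guide and 4.48% without, lower in 10 of 11 pairs (exact p = 0.00879; 0.0183 adjusted), but with an increase of at least 5 points required the share fell by 0.325 points and no longer passed (0.397 adjusted).

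Messages of ribosomal proteins were called most often among the 14 gene lists fixed beforehand. By the calls of the authors' deposited table, 28.9% of the 6078 listed sites in 74 ribosomal protein genes were called in a library on average, at percentile 100 of 10000 random lists matched on number of sites (median 17.6%; two-sided tail share 0.0002, or 0.0026 adjusted over the 13 lists with sites). Glycolytic enzymes, 25.0% in 17 genes, lay at percentile 99.99 and histones, 22.2% in 10 genes, at percentile 99.81, and both passed adjustment (0.0026 and 0.0173). These calls turned with the size of the change required. With an increase of at least 5 points, the share of sites called fell to 7.56% for ribosomal proteins, 8.52% for glycolysis and 8.75% for histones, at percentiles 0, 0 and 0.22, and splicing factors went from percentile 89.5 to 0. Secretory pathway genes (percentile 98.8), cell cycle genes (85.6), nuclear-retained RNAs (60.1), genes with inverted repeats (38.9), known editing substrates (30.9), tumour suppressors and oncogenes (29.4), RNA sensors (16.0) and the ADAR family with RAB7A (14.3) did not pass on the mean over libraries. That mean hides differences between libraries. In the 4 full-length ADAR2 libraries genes with inverted repeats lay at percentiles 97.67 to 100, nuclear-retained RNAs at 95.61 to 99.48, and glycolysis at 44.55 to 68.6. In the 8 MCP-ADAR1 libraries genes with inverted repeats lay at 0.03 to 19.9. Nuclear-retained RNAs lay at 0.39 and 2.12 in MCP-ADAR1 DD (E1008Q)-NES, but at 97.73 and 96.48 in MCP-ADAR1 DD-NLS. In the remaining MCP-ADAR1 libraries they lay at 64.5 to 79.71. Glycolysis lay at 98.46 or higher in the 18 libraries that are not full-length. Ribosomal proteins lay at 90.52 to 99.26 in the full-length libraries. These differences between libraries were not tested. Markers of other cell types lay at percentile 99.1 with 5 of 18 genes listed (0.0611 adjusted), and 0 sites were in the mitochondrial genome. Each percentile describes these libraries only.

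Genes known as natural editing substrates were edited both at known positions and elsewhere. In COPA, of the coatomer, K318R (chr 1, position 160311991) rose above the untransfected level by 42.2 ± 22.0 points (SD, 22 libraries) and was called in 20 libraries. In CCNI, a cyclin, K274R (chr 4, position 77048532) gained 39.6 ± 21.4 points and the known R75G site (chr 4, position 77058527) 36.8 ± 19.0 points, and in GIPC1 the T62A site (chr 19, position 14482793) gained 27.8 ± 20.1 points. The ADAR and ADARB1 messages were edited too. A 3′ UTR site of ADAR (chr 1, position 154583325) gained 18.5 ± 13.4 points and was called in 17 libraries of the authors' deposited table. ADARB1 K618R (chr 21, position 45220941) gained 13.6 ± 23.4 points from an untransfected level of 13.7%, in the gene the ADAR2 constructs derive from, so reads of the transfected message can count there. RAB7A itself had a T64A site (chr 3, position 128806381), away from the target, that gained 18.2 ± 14.1 points and was called in 19 libraries.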

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

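The tests of guide pairing, of a more active deaminase, of compartments and of unspliced RNA had bounds set before their results were seen; the tests of depth and of ADAR2 sites were chosen only after the results were seen, and the random splits were planned, with their bound written afterwards.

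The guide went with more called sites in full-length ADAR2 than in MCP fusions, by 3.96-fold in 2 pairs against 1.24-fold in 8. The difference of log2 ratios was 1.67 (exact permutation p = 0.0222, the smallest possible, 0.124 after adjustment over 13 tests). With so few pairs it could hardly have passed adjustment. Depth as the whole cause of the rise is argued against, since at 112103 sites chosen from MCP libraries the mean increase in share, which depth does not scale, was 2.12 times as high with guide in wild type (95% interval over genes 2.07 to 2.17) and 2.90 times in E488Q (2.86 to 2.94). Pairing of the guide at each of the 5120 sites gained in both pairs cannot be told apart, since 63.0% of them were called in a deaminase library without any guide, over the bound of 50% set beforehand, but so were 77.97% of all listed sites, and that bound took no account of this. A more active deaminase in the cultures with guide cannot be told apart either, since 44.5% of the sites from MCP libraries were higher with guide in both pairs (1.76% lower), under the bound of 60% set beforehand, but shares of 0 with guide at 46.0% of these sites left 54.0% as the highest value possible, so the bound could not have been met. At 23127 sites of MCP-ADAR2 libraries, a set chosen after that value was seen, 67.8% were higher and 0.938% lower.

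In the Cas13b fusion called sites went the other way with its gRNA, with a log2 ratio of -1.19 in 1 pair against rises in both full-length pairs, a difference that was not tested; depth is argued against by a mean increase at the same 112103 sites of 0.627 times that without gRNA (95% interval over genes 0.623 to 0.631).

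The NLS went with a smaller loss of called sites in E-to-Q than in wild-type fusions, 1.58-fold against 3.84-fold. This is the same contrast as a larger E-to-Q gain in NLS than in NES fusions. The difference of log2 ratios was 1.28 either way (exact permutation p = 0.0286, the smallest possible, 0.124 after adjustment). For the loss itself, depth is argued against by 37331 sites chosen from full-length and Cas13b libraries, where the mean increase with NLS was 0.642 times that with NES (lower in 8 of 8 pairs, 0.443 to 0.968 times, exact p = 0.00781). Access to unspliced RNA predicted a smaller loss at intronic sites. The 1454 intronic sites lost less than exonic ones in 8 of 8 pairs (difference of log2 ratios 0.17 ± 0.08, exact p = 0.00781). They too fell, to 0.670 times, against 0.595 times at exonic sites, so such access is a candidate for this difference and not for the loss. Intronic here means in a gene outside annotated exons, and reads there were not shown to be unspliced. Access to each compartment's RNA cannot be told apart from no such effect with the list of nuclear-retained RNAs, whose difference of 0.17 ± 0.28 had the predicted sign in 6 of 8 pairs (exact p = 0.0859). Different amounts of NLS and NES protein were not measured here and stay open.

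In random splits of the 16 MCP libraries into 8 and 8, a split took the place of 1 factor and the other 3 factors stayed in the fit, so the effect of the replaced factor entered the spread of the other splits. For the limma counts by enzyme 1 of 50 splits, the real one, gave as many sites (262829, highest other 135341). By variant it was also 1 of 50 (154870, highest other 41210). A large effect of the replaced factor can lower the counts of the other splits, so these ranks alone do not exclude chance. For localisation 2 of 50 gave as many (14555, highest other 130009) and for guide 2 of 50 (3, highest other 58242), a share under 0.05 that rests on 1 other split each. Those splits called far more sites than the real ones, which points to a structure of the samples. Beyond the factors kept in the fit, the one for guide followed the products of enzyme with variant and of enzyme with localisation equally (correlation 0.707 with each), and the one for localisation followed these and localisation itself (0.577 with each). The median of the other splits was 0 for each factor.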

How the results depend on the processing

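The p threshold of 0.001, the 10-point increase without a p, the logits, the 2% minimum, MCP pairs alone and the fits within NES or NLS were chosen after seeing the data; the rest were planned before the data were examined. The directions of the E-to-Q, NLS and ADAR2 effects on called sites held, past the threshold, under every alternative run. Of the recomputed values, 268 of called sites, factors, lists and overlap and 43 of neighbouring bases and regions kept their direction and side of the threshold, or moved little. Leaving out a matched pair gave log2 ratios of 1.87 to 2.09 for E-to-Q, -1.46 to -1.13 for NLS, 0.30 to 0.65 for the guide and -2.51 to -2.21 for ADAR2. The guide effect passed the threshold only without the Cas13b pair (0.65). Leaving out an untransfected run moved no library by more than 3 called sites, for instance those of MCP-ADAR1 DD-NES without guide to 116158 and those of MCP-ADAR2 DD (E488Q)-NLS with guide to between 38077 and 38079.

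With an increase of at least 5 points, called sites were 13574 in MCP-ADAR1 DD-NLS without guide, 1996 and 3092 in MCP-ADAR2 DD-NLS without and with guide, and 15 with the Cas13b gRNA alone; at an adjusted p under 0.05 GFP had 12. The same 5 points changed the side of the random lists' middle for known editing substrates (percentile 97.2), inverted repeats (90.8), nuclear-retained RNAs (2.7), ribosomal proteins (0), glycolysis (0), secretory genes (9.24), cell cycle (8.51), histones (0.22) and splicing factors (0). Highly expressed genes can pass at small changes where reads are many, but the cause was not tested. It also turned the sign of differences in neighbouring bases, none past the threshold in either setting: 5′ A by variant (1.14 points) and by localisation (-1.39), 5′ U by guide (-0.014) and by enzyme (0.447), 3′ G by guide (-0.0049) and UAG by guide (-0.113). The lower share of 5′ UTR sites with guide (-0.325 points, adjusted exact p = 0.397) and the higher share of UAG with NLS (2.21, 0.056) no longer passed, and 5′ C by variant did (-3.92, 0.0489).

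Limma called 244090 sites by enzyme in NES and 69156 in NLS libraries alone, and by variant 44656 in NES and 55787 in NLS libraries alone. By localisation it called 22601 without trend, 6894 on logits with a pseudocount of 0.05 and 24355 with the interaction. By guide limma called 0 without trend (12126 at an unadjusted p under 0.05), 0 with the interaction (14302), 0 in NES (11471) and 0 in NLS (13924) libraries alone, 7 and 1 on logits with 0.01 and 0.05, and 5 at a mean share of at least 2%. The causes of these shifts were not tested. No paired analysis of replicates was possible because the labels number runs of 1 untransfected library only, and the pairs used are of constructs. Not run, for want of read counts, were the minima of 20 and 50 reads, thinning to equal coverage, the exact test per site, a prior count of 2, Bonferroni adjustment of that test, lists matched on coverage and a split control.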

Other observations

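The comparisons of full-length ADAR2 with MCP-ADAR2 fusions, of textbook recoding sites and of MALAT1 and NEAT1 were chosen only after the results were seen, and the list of textbook sites was written from general knowledge after part of the data had been seen.

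Full-length ADAR2 edited different parts of messages than its deaminase domain fused to MCP. In its 4 libraries 39.6% ± 6.17 of called sites lay in 3′ UTRs and 9.32% ± 1.51 in 5′ UTRs, against 22.2% ± 2.19 and 3.24% ± 0.389 in the 8 MCP-ADAR2 libraries, and 48.0% ± 8.05 lay in coding sequence against 73.2% ± 1.71. Its sites had U on the 5′ side in 19.9% ± 1.12 of cases, against 26.6% ± 1.096. Each difference had an exact permutation p of 0.00202, 0.00657 after adjustment over 13 features. This test took libraries as units. In both groups they are the same constructs with and without guide, so they are not independent and the p-value describes these libraries only. The groups also differ in the fusion to MCP, the localisation signal and the guide used. Without any guide, 3′ UTR sites made up 48.5% and 38.8% in the 2 full-length libraries and 19.6% to 25.5% in the 4 MCP-ADAR2 libraries, so the guides do not account for this difference.

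Most textbook recoding sites in the table rose more in the full-length enzyme. Of 29 listed, 11 were in the table, 10 had a higher mean in the full-length libraries, and at 7 every full-length library lay above every other one. Selection of sites into the table partly sets this tally. SRP9, CYFIP2, TMEM63B, COG3 and BLCAP sites were called in full-length libraries and in none of the 18 other deaminase libraries. COG3 was called in 2 full-length libraries and BLCAP in 1. At CYFIP2 K320E (chr 5, position 157309800), in a regulator of actin assembly, the 4 full-length libraries averaged 67.6% ± 10.6 and the 18 other deaminase libraries 0.444% ± 1.31. FLNA Q2341R (chr X, position 154351582), in filamin A, stood at 66.0% ± 11.5 and 11.2% ± 12.1, GIPC1 T62A at 63.2% ± 13.3 and 20.3% ± 10.5, COG3 I635V (chr 13, position 45516236), in a Golgi tethering complex, at 57.6% ± 19.6 and 2.86% ± 6.03, and SRP9 I64V (chr 1, position 225786910), in the signal recognition particle, at 25.5% ± 5.82 and 0.462% ± 0.578. The groups overlapped at ZNF358 K382R (19.5% ± 18.8 and 14.3% ± 7.40), AZIN1 S367G (12.4% ± 10.7 and 3.01% ± 2.59) and BLCAP Q5R (12.7% ± 4.56 and 4.08% ± 2.38), and CCNI R75G (chr 4, position 77058527) went the other way, with 19.3% ± 19.1 and 41.1% ± 17.0.

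By the mean increase over all listed sites, the full-length libraries were not more active than the 18 other deaminase libraries as a group. The increase over all sites was 3.38 points in the full-length and 4.23 points in the other libraries. At the textbook sites it was 38.4 ± 9.23 and 8.78 ± 3.23 points, a ratio 5.47 times that over all sites. Among full-length libraries, only ADAR2 (E488Q) with guide, with 7.87 points, lay above the others' mean. Without it the increase over all sites was 1.88 points and the ratio 8.68 times. The others include MCP-ADAR1 libraries, whose E-to-Q forms called 70.0% of the listed sites. The mean over all sites thus leans on sites that ADAR1 edits, and it cannot exclude a higher activity of full-length ADAR2. Mean shares over all sites were 0.938% to 3.29% in MCP-ADAR2 libraries. Full-length libraries had 1.18% to 2.78%, and 8.03% in ADAR2 (E488Q) with guide. Median levels of called sites went the other way, with 13.2% to 15.8% in full-length and 5.62% to 12.3% in the other libraries. A higher activity than in MCP-ADAR2 fusions alone was not tested and stays open. A candidate explanation is the domains outside the deaminase domain, which only the full-length enzyme has and which bind double-stranded RNA. The increase at textbook sites divided by that over all sites was 14.9 higher in the 4 full-length libraries (17.8 ± 12.8 against 2.87 ± 1.62), or 8.81 higher without wild-type ADAR2 without guide, though the ranges overlap, with 6.58 as the lowest full-length and 7.91 as the highest other value. This quotient restates the pattern on the sites that showed it, so these domains cannot be told apart from other differences between the constructs or their amounts. The guides are argued against, since without any guide CYFIP2 K320E stood at 62.7% and 55.6% in full-length ADAR2 and at most 3.45% in the 9 other deaminase libraries.

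MALAT1, a long RNA held in the nucleus, was edited more by NLS fusions. Over its 33 sites the mean share was 3.23% ± 3.47 in the 8 NLS and 1.11% ± 1.26 in the 8 NES libraries, higher in 8 of 8 pairs by 2.13 ± 2.27 points (exact sign-flip p = 0.00781). NEAT1, also nuclear, had 1.07% ± 0.959 and 0.862% ± 0.612 over 95 sites, higher in 4 of 8 pairs (exact p = 0.211). Over all 471 sites of nuclear-retained RNAs, which include both, the increase with NLS was 0.670 times that with NES.

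The few calls in control libraries recurred at shared positions. By the calls in the authors' deposited table, at least 1 control called each of 29 sites, the GluR2 adRNA and the Cas13b gRNA alone shared 16 of their 18 and 23, and the MS2 and GluR2 adRNAs shared 12. The same untransfected mean set the direction of all these calls, and the reference behind their p-values is not named.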
